A study of Caenorhabditis elegans with 2 samples.

How the data were processed

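The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of HPL-2, a worm homologue of heterochromatin protein HP1, in Caenorhabditis elegans. The larvae were first-stage (L1) animals that had hatched without food after bleaching, taken as whole organisms of mixed sex. Per the labels, the strain YL474 carries the lin-35 allele n745, the unc-119 allele ed3 and an integrated array that holds HPL-2 fused to GFP and FLAG under the ges-1 promoter, with unc-119(+) as its marker. The description in the labels names the tagged protein as the target, while their antibody entry names hpl-2, so whether GFP, FLAG or HPL-2 itself was precipitated is unknown here. The ges-1 promoter is an intestinal promoter. If the tag was precipitated, the protein came from cells that express the array. If HPL-2 itself was, the endogenous protein of all tissues contributes. The chromatin came from the whole animal in either case. The 2 libraries are biological replicates 1 and 3 of 1 group, per the labels, with a library size range of 150 to 350. No input, untagged or other control library is among the samples, and no second biological condition was analysed here.

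The authors deposited, for each library and for both libraries pooled, a list of 30000 candidate regions that served as input to an irreproducible discovery rate (IDR) analysis. They also deposited a thresholded list of regions that pass it. Each kind of list exists on the builds ce11 and ce10. Per the deposited file listings, the candidate regions of a library were derived from its own alignments and 1 control file. That control file was not analysed here. The aligner, the peak caller and the IDR settings are not given in the sources used here. For every region the deposited lists give a signal, which is an enrichment value by the region's caller, and the −log10 of a q-value. In the thresholded ce11 list, 849 of 857 regions share the highest −log10 q-value, 3.23, in the authors' deposited list, so regions were ranked by signal. The signal is the authors' own value per region and was used to rank, filter and describe regions within 1 list, and across lists only in rank correlations and to compare the ce11 and ce10 versions of the pooled calls. Ranking the pooled ce11 candidates by signal showed that the thresholded set is exactly its top 857 regions, and in ce10 exactly the top 766. The thresholded set is therefore a signal cutoff on the pooled list, and a region in it need not be strong in both libraries. The lists hold no read counts, so the sequencing depth of either library is unknown.

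The thresholded ce11 list is called the reproducible regions below, and the other 29143 pooled candidates are the background. The background was scored by the same caller on the same reads, but the mappability of single regions was neither measured nor matched. The background was itself picked for enrichment, so a difference from it is not a difference from the genome. Regions in a candidate list have a fixed width in nearly all cases (376 bp in the pooled ce11 list), so positions were taken from the summit. Coordinates are 1-based on ce11, which has the sequence of WBcel235. Genes and transcripts came from Ensembl release 115, and sequence with lower-case repeat masking from the RefSeq copy of WBcel235. No coordinates were converted between builds. Overlaps, annotation and tests ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

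A region counted as lying at a promoter when its summit was within 500 bp of the 5′ end of a protein-coding transcript. It counted as near a noncoding gene when the summit was within 250 bp of it, and GC content, repeat masking and motifs were read within 100 bp on either side of the summit. Distal chromosome means the outer 25% of an autosome at each end. Shares were compared with the background by Fisher's exact test, two-sided. Mean GC and masked sequence, and the median log2 signal, were compared by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05. Overlap of the libraries' top-ranked regions, with at least 1 bp shared, was set against 1000 circular shifts of replicate 3 along each chromosome, whose smallest possible p is 0.001. Within each family (8 noncoding classes, 10 motifs, 18 gene lists) p-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Intervals on shares are Wilson intervals at 95%. Intervals, and the upper limit for a count of 0 (3 counts of the total), cover counting error only. Regions and genes are not replicates: p-values over them describe these lists, and the spread between animals is seen only in the 2 libraries.

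The gene lists were fixed before the data were examined. They cover marker genes of intestine, germline, neuron, muscle and hypodermis, synMuv and heterochromatin factors, starvation, insulin and autophagy genes, and families defined by gene name: ribosomal proteins, histones, cuticle collagens, C-type lectins with lysozymes and antimicrobial peptides, chemoreceptor GPCRs, F-box and MATH-BTB proteins, heat shock proteins, nuclear hormone receptors, homeobox factors, proteasome with vacuolar ATPase subunits, and neuropeptides. A list of the 3 transgene loci (ges-1, hpl-2, unc-119) had no member with a candidate region and was not tested. The name lin-4 in the starvation list matched no protein-coding gene. The background for gene lists was the 7918 protein-coding genes with any pooled candidate at a 5′ end. Motifs, also fixed in advance, were extended GATA (TGATAA), plain GATA (WGATAR), a GAGA repeat (GAGAGAGA), an Sp1-like GC box (GGGCGG), an E2F-like site (TTSGCGC), the cell cycle homology region or CHR (TTYGAA), an E-box (CACGTG), AP-1 (TGASTCA), a T tract (TTTTTTTT) and a scrambled control (TAGTAA). The genes named are those nearest to the 20 strongest reproducible regions, up to 4 members per list with the strongest region at a 5′ end, and the transgene loci and lin-35 in any case. Any other gene named was chosen after its values were seen.

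Alternatives were the 428 strongest reproducible regions, the top 857 regions of each library alone, the 14572 weakest background regions, random positions, other distance and window limits, other gene backgrounds, stricter overlap rules, and ce10. For the motifs, a background matched on GC content was added after seeing the data, with 2 regions drawn per reproducible region in bins of 2.5 percentage points, which left out 1 reproducible region. The functions were tested on simulated data drawn from the real candidates. With nothing planted, 4.5% of 200 simulated promoter shares (857 regions each) passed the threshold, any of the gene lists was called in 4% of 200 draws from the 7918 genes, any motif in 3% of 100 draws, and the GC difference in 8% of 100 draws of 857 regions. A planted gain of 5 percentage points in promoter share gave the same counts in every draw and passed the threshold, so it yields no recovery rate. With members of a list given 6 times the weight of other genes, the call was made in 100% of draws for the 69 ribosomal protein genes, 98% for the 43 proteasome and vacuolar ATPase genes, 83% for the 22 intestine genes and 45% for the 11 heat shock genes. At 3 times the weight, the intestine list was called in 20% of draws. Genes were drawn independently in these simulations, whereas neighbouring genes in the data can share a region. The rates for gene lists leave out that dependence.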

Results

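The data set held 2 HPL-2 ChIP-seq libraries, biological replicates 1 and 3 of a single group. They came from starved L1 larvae of a strain with GFP-tagged HPL-2 and the lin-35 allele n745. No strain with wild-type lin-35 was among the samples. Whether the tag or HPL-2 itself was precipitated is not settled by the labels. The comparisons the data set allows are between the libraries, between the reproducible regions and the weaker candidate regions of the same experiment, and between genome builds. The ce11 set of reproducible regions had 857 members, with a signal from 37.9 to 253 and a median of 51.2. By chromosome, there were 155 on I, 127 on II, 157 on III, 134 on IV, 131 on V and 153 on X. Chromosome III had the densest coverage at 11.4 regions per Mb and chromosome V the sparsest at 6.26.

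The strongest regions lay mainly on the X chromosome and away from promoters. Of the 20 regions with the highest signal, 12 were on X, and 11 of those 12 had a summit more than 500 bp from any protein-coding 5′ end. The strongest of all, X 11937458 to 11937640, had a signal of 253 and lay between genes, 1375 bp from the 5′ end of F55G7.5. It was followed by X 11094111 to 11094327 (signal 224, intergenic, nearest 5′ end W02H3.3) and X 13700804 to 13701009 (signal 213, intergenic, nearest 5′ end K02D3.1). The only promoter region among the 12 was X 5841227 to 5841411 (signal 202), whose summit was 267 bp from the 5′ end of puf-9, a Pumilio family RNA-binding protein gene. The others on X were nearest to ZK899.6 (signal 200), ins-39 (194), C41A3.2 (185, in an exon of pks-1), Y41G9A.17 (181, in its intron), xol-1 (178), F22H10.2 (168), mom-1 (167, in its intron) and nspc-17 (164). The gene xol-1, the X-dosage switch of sex determination, had its 5′ end 4921 bp from that summit at X 8036392.

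On the autosomes, 8 regions were among the 20 strongest. On chromosome II, the promoter of iff-2, a translation factor eIF5A gene, had a region at 8561360 to 8561516 with a signal of 199. The promoter of cdc-48.1, encoding an AAA ATPase, had 1 at 10563474 to 10563654 with a signal of 184. The ribosomal protein genes rpl-3 (signal 176) and rpl-35 (170) had theirs at III 3867510 to 3867645 and III 7854607 to 7854767. The regions at II 5844641 to 5845016 (signal 182, nearest protein-coding gene ZK1248.17) and II 5543505 to 5543610 (181, nearest ins-13) lay beside sls-2.1 and sls-2.2, genes of the spliced leader SL2 RNA. The remaining regions were in an exon of C34C12.2 at III 3456323 to 3456512 (signal 192, nearest 5′ end C34C12.1) and in an intron of Y111B2A.12 at III 12612505 to 12612880 (signal 164).

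**Figure D1:**
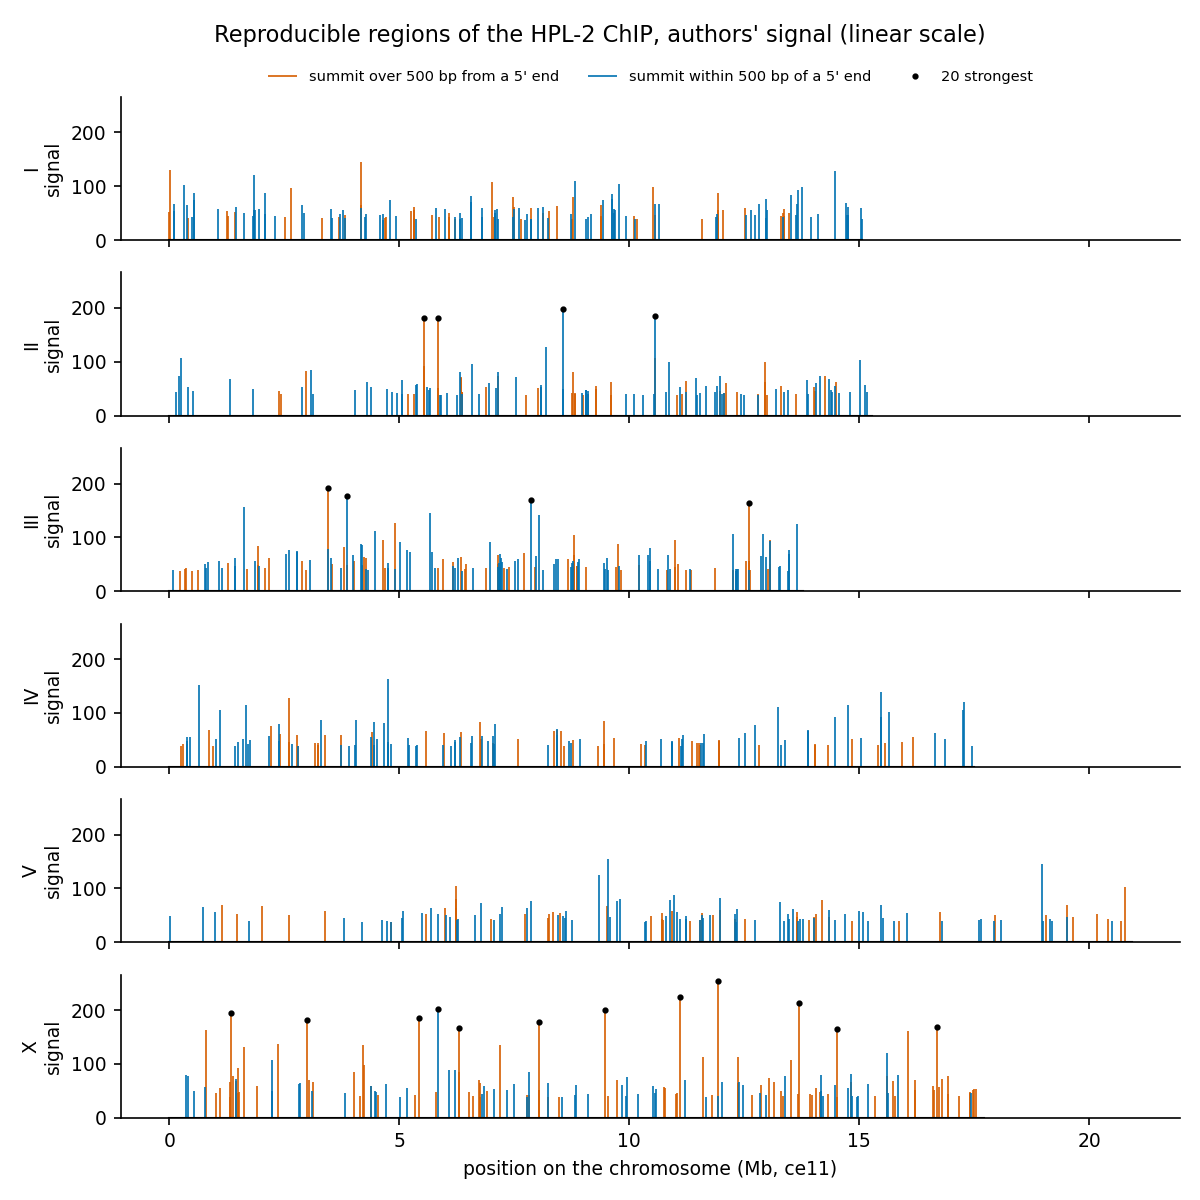
Each vertical line is 1 of the 857 reproducible regions, at its ce11 position in Mb (horizontal) with its height giving the authors' signal (vertical, linear scale, 1 panel per chromosome). Blue lines have a summit within 500 bp of a protein-coding 5′ end, orange lines do not, and dots mark the 20 strongest, of which 12 are on X.

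How far the libraries ranked the same places first was asked with the top 857 regions of each. Of the replicate 1 regions, 402 (46.9%) overlapped a top region of replicate 3, whereas circular shifts gave a mean of 0.629% and at most 1.75% (permutation p = 0.001, the smallest that 1000 shifts can give). Regions drawn at random from the replicate 3 candidates, a null chosen after seeing the data, gave a mean of 3.26% and at most 5.25%. Overlap was highest among the strongest regions, with 66.0% of the top 50 shared and 43.7% of the top 1600. The libraries did not contribute evenly to the reproducible set: 86.2% of it lay in the top 857 of replicate 1 and 56.5% in the top 857 of replicate 3. Over the 839 reproducible regions with a candidate in both libraries, Spearman's rho of the signals was 0.265. Choosing regions by pooled signal can lower this value, so it does not measure how well the libraries rank all candidates. Replicate 3 had no candidate at all for 18 of the 857 regions. The signal of replicate 3 ran lower, from 2.01 to 58.0 against 6.69 to 198 in replicate 1, but its scale is not comparable between lists. Of the 857 reproducible regions, 600 overlapped a top-1714 region of both libraries.

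**Figure D2:**
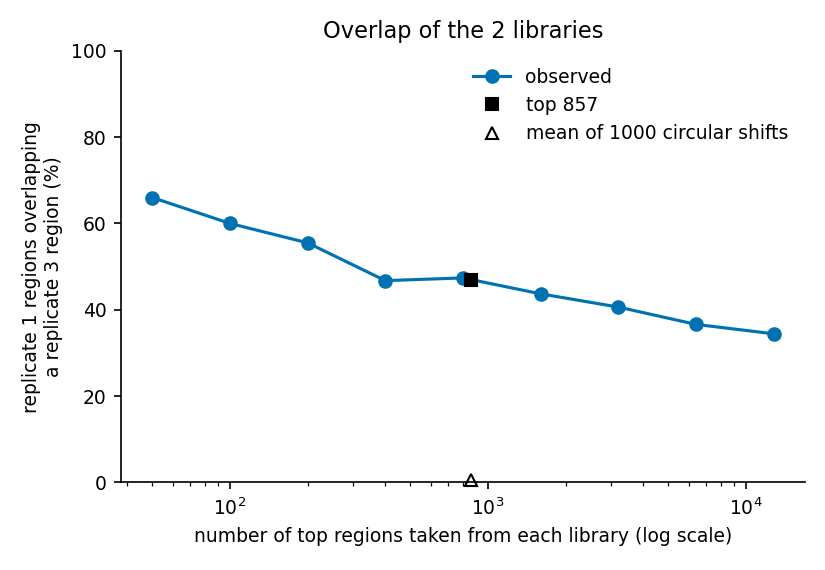
The share of replicate 1 regions that overlap a replicate 3 region (vertical, percent) is plotted against the number of top regions taken from each library (horizontal, log scale). The share falls from 66.0% at 50 regions to 34.4% at 12800, and the open triangle is the mean of 1000 circular shifts at 857 regions, 0.629%.

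Reproducible regions were at gene starts more often than background regions. Of the reproducible regions, 503 of 857 (58.7%, Wilson interval 55.4 to 61.9) had a summit within 500 bp of a protein-coding 5′ end, against 30.3% of the 29143 background regions. The share was 28.4 percentage points higher (Fisher's exact p = 5.12e-64). The median distance from the summit to a 5′ end was 324 bp in the reproducible regions and 1081 bp in the background. Exons outside promoters held 2.45% of reproducible and 15.1% of background regions, introns 11.7% and 25.1%, and intergenic sequence 27.2% and 29.5%. The top 857 regions of each library averaged 55.2% ± 2.97 (SD, n = 2) at promoters, against 29.6% ± 0.163 (SD, n = 2) in the candidates below them, so the difference exceeded the spread between replicates.

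Promoter regions were not stronger than the rest. Their median signal was 51.7, and that of the other reproducible regions was 50.99, a log2 difference of 0.02 (permutation p = 0.557). With the signal of the overlapping region in replicate 3, the log2 difference was −0.11 (permutation p = 0.0614).

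The distal parts of the autosomes, where repeats and H3K9 methylation are concentrated in this species, held fewer reproducible regions than background regions. They contained 293 of 704 autosomal reproducible regions (41.6%, Wilson interval 38.0 to 45.3) and 47.9% of the background (difference −6.26 percentage points, Fisher's exact p = 0.00112). In the top regions of the single libraries the share was 40.2% ± 0.805 (SD, n = 2), against 47.9% ± 0.663 (SD, n = 2) in the candidates below them. The distal share was matched on neither promoter location nor GC content, so whether it differs apart from these was not tested. Pooled candidates are 376 bp wide in nearly all cases, so broad domains on the distal parts were not measured. The X chromosome as a whole held 153 of 857 reproducible regions (17.9%, Wilson interval 15.4 to 20.6) and 18.3% of the background, which did not differ (Fisher's exact p = 0.788). Its share was 21.3% among the 428 strongest regions, which turned the difference to 2.99 percentage points above the background (Fisher's exact p = 0.116).

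Sequence at the summits was GC-rich and poor in masked repeats. Mean GC content within 100 bp of the summit was 42.6% ± 6.73 (SD over 857 regions) in the reproducible set and 34.9% ± 6.67 (SD over 29143 regions) in the background, a difference of 7.74 percentage points (permutation p = 1e-05, the smallest that the resamples can give). It narrowed to 4.45 points when sequence within 200 bp was read. Masked repeats covered 24.6% of the sequence around reproducible summits and 36.0% around background summits, a difference of −11.4 percentage points (permutation p = 1e-05, again the smallest possible). The masked share was matched on neither GC content nor mappability, so whether it differs apart from these was not tested. In the single libraries' top regions, GC averaged 41.3% ± 1.73 (SD, n = 2) and masked sequence 26.1% ± 2.44 (SD, n = 2). The corresponding values for the candidates below them were 34.8% ± 0.744 and 35.9% ± 2.32 (SD, n = 2).

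Genes for small structural RNAs were more frequent next to reproducible regions than next to background regions. Genes for snoRNAs, which guide RNA modification, lay within 250 bp of 45 of the 857 reproducible regions (5.25%) and of 0.425% of background regions (odds ratio 12.97, adjusted p = 3.51e-30 by Fisher's exact test). For snRNA genes, which in this annotation include the SL2 spliced leaders, the shares were 2.33% and 0.175% (odds ratio 13.6, adjusted p = 1.6e-14 by Fisher's exact test). For tRNA genes they were 3.85% and 1.17% (odds ratio 3.39, adjusted p = 2.39e-08 by Fisher's exact test). The class of other noncoding RNAs was near 163 regions (19.0%, against 5.96%), and miRNA genes were near 6 (0.700%, against 0.182%, adjusted p = 0.0076 by Fisher's exact test). In contrast, genes of piRNAs, the small RNAs of the germline, were near 12 regions (1.40%, against 4.13%, adjusted p = 1.45e-05 by Fisher's exact test), and pseudogenes near 5 (0.583%, against 2.31%, adjusted p = 0.000214 by Fisher's exact test). Nuclear rRNA genes were near 0 of the 857 and 0 of the 29143 regions. Among the 428 strongest regions the calls for miRNA genes (adjusted p = 0.623) and pseudogenes (adjusted p = 0.0936) were lost, both by Fisher's exact test. For snoRNA genes the difference of 4.83 percentage points was 2.97 in the top regions of replicate 3 alone. None of these classes was compared with a background matched on GC content, so whether they differ apart from GC was not tested.

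Among the sequence motifs, 4 were more frequent at reproducible summits than in the background, 3 of them also against a background matched on GC content, which was chosen after seeing the data. In the matched comparison 856 reproducible regions were set against 1712 background regions. The GAGA repeat was present at 10.04% of reproducible and 2.58% of background summits (adjusted p = 6.83e-24 by Fisher's exact test). The E2F-like site, the type bound by the E2F and DP partners of LIN-35, was at 9.57% and 2.59% (adjusted p = 1.08e-21 by Fisher's exact test). The E-box was at 8.63% and 4.14%, and the Sp1-like GC box at 10.04% and 3.66%. Matched on GC, the background shares were 5.26% for the GAGA repeat (adjusted p = 5.03e-05), 2.75% for the E2F-like site (8.64e-12) and 5.55% for the E-box (0.0132), while the GC box lost its call (7.48%, adjusted p = 0.1005), all by Fisher's exact test. Less frequent were the CHR element bound by LIN-54 (41.4% against 56.9%, adjusted p = 9.62e-19 by Fisher's exact test), the T tract (12.7% against 25.4%), extended GATA (16.2% against 21.4%) and plain GATA (33.02% against 39.5%), the last 2 being sites of intestinal GATA factors. The scrambled control, which is rich in A and T, was also less frequent (3.73% against 8.20%, adjusted p = 4.21e-07 by Fisher's exact test), with a lower odds ratio (0.434) than CHR (0.536) or extended GATA (0.7095). Matched on GC, no motif was called less frequent, with background shares of 39.1% for CHR (adjusted p = 0.414), 12.6% for the T tract (0.9498), 15.2% for extended GATA (0.657), 33.6% for plain GATA (0.840) and 5.43% for the scrambled control (0.129), all by Fisher's exact test. AP-1 sites did not differ (1.63% against 2.03%, adjusted p = 0.536 by Fisher's exact test). In the top regions of replicate 3 alone, extended GATA was 2.62 percentage points above its background (adjusted p = 0.0749) and plain GATA differed from it by −0.367 (adjusted p = 0.859), both by Fisher's exact test. Plain GATA also missed the threshold when sequence within 200 bp was read (difference −3.05, adjusted p = 0.0824 by Fisher's exact test).

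**Figure D3:**
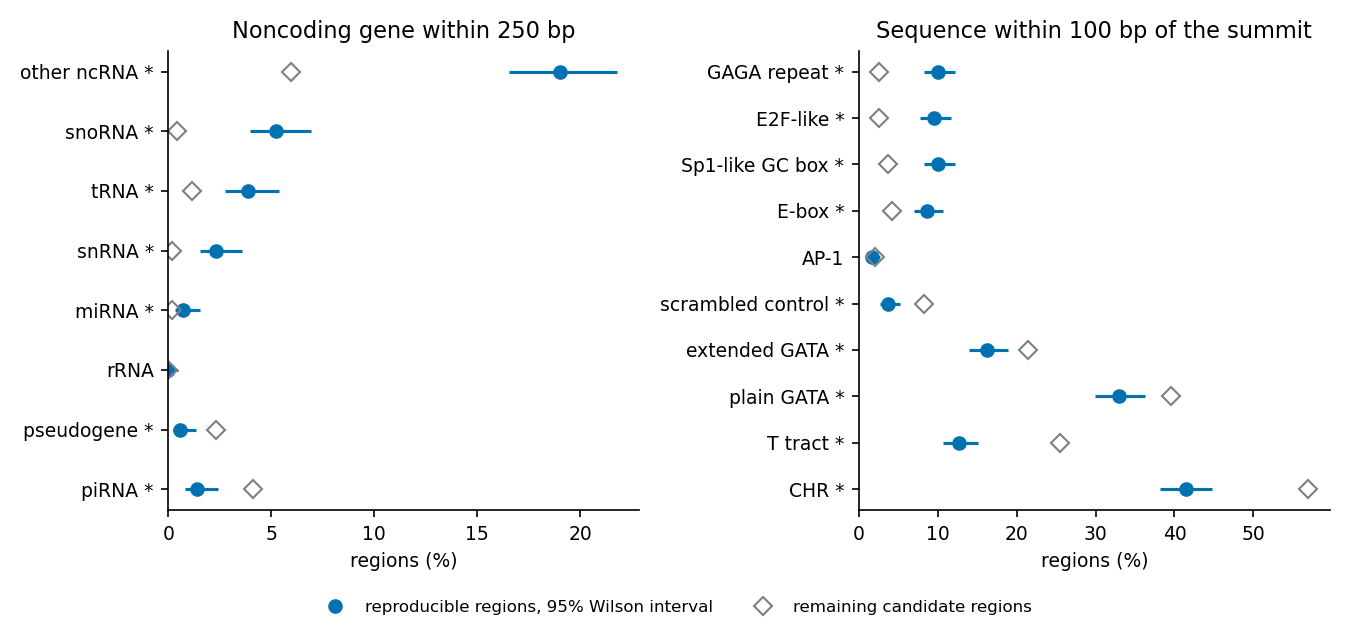
Blue points with lines give the percentage of the 857 reproducible regions, with 95% Wilson intervals, that lie near each noncoding gene class (left) or hold each motif (right). Grey diamonds give the percentage of the 29143 background regions, and asterisks mark adjusted p below 0.05. The snoRNA share of 5.25% lies above its background of 0.425%, and the CHR share of 41.4% below its background of 56.9%.

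Ribosomal protein genes stood out among the gene lists. A reproducible region lay at the 5′ end of 52 of the 69 ribosomal protein genes that had any candidate region (75.4%), against 7.84% of the other genes (odds ratio 36.0, adjusted p = 5.68e-41 by Fisher's exact test). The strongest were at rpl-3 (signal 176), rpl-35 (170), rpl-20 (163) and rpl-15 (153). In the top regions of the single libraries the share was 70.0% in replicate 1 and 59.7% in replicate 3. With a limit of 250 bp it was 13 of 25 genes (52.0%). Most of the 52 genes thus had no reproducible summit within 250 bp of a 5′ end, whereas other genes with one went from 615 to 390. When only the nearest gene was counted, the share was 32 of 44 (72.7%), so some of the 52 genes have a region nearer to another gene. Across all genes, 667 of the 7918 with a candidate region had a reproducible one (8.42%).

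The other over-represented lists were proteasome and vacuolar ATPase subunits, tested as 1 list, and heat shock proteins. Proteasome and vacuolar ATPase subunits had reproducible regions at 13 of 43 genes (30.2%, adjusted p = 0.000195 by Fisher's exact test), led by rpn-3 (signal 60.2), vha-8 (57.9), rpt-2 (50.3) and vha-15 (49.9). Heat shock proteins had them at 4 of 11 genes (36.4%, adjusted p = 0.0367 by Fisher's exact test): hsp-1 (signal 121), hsp-3 (89.05), hsp-110 (60.2) and hsp-90 (52.9). The genes rpn-3 and hsp-110 share the same region between their divergent 5′ ends. In replicate 3 alone neither list passed (adjusted p = 0.12 for both by Fisher's exact test), with the proteasome and vacuolar ATPase share down to 17.5% (7 of 40) and the heat shock share at 33.3% (3 of 9). The proteasome and vacuolar ATPase list was lost among the 428 strongest regions (5.71%, adjusted p = 0.925 by Fisher's exact test). The heat shock list was lost with a 250 bp limit (adjusted p = 0.747), among genes with a 3- or 4-letter symbol (0.0663) and when only the nearest gene was counted (0.284), all by Fisher's exact test.

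The lists called under-represented were chemoreceptors and the group of lectins, lysozymes and antimicrobial peptides. Chemoreceptor GPCR genes had a reproducible region at 3 of 233 genes (1.29%, adjusted p = 3.04e-05 by Fisher's exact test): srh-16 (signal 52.3), srz-97 (41.1) and srz-62 (38.9). The region at srz-97 also lies beside the snRNA gene F08H9.11. The C-type lectins, lysozymes and antimicrobial peptides had 0 of 84, which allows a share of up to 3.57% (adjusted p = 0.00503 by Fisher's exact test). The second call was lost in replicate 3 alone (2 of 94, adjusted p = 0.167), among the 428 strongest regions (still 0 of 84, 0.195) and with the 250 bp limit (0 of 54, 0.0906), all by Fisher's exact test.

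The list of synMuv and heterochromatin factors includes hpl-2 and lin-35 themselves but is not a single pathway. Reproducible regions lay at 5 of its 22 genes with a candidate region (22.7%), which did not pass after adjustment (adjusted p = 0.099 by Fisher's exact test). These were lin-54 (signal 110), lin-53 (76.1), lin-35 (60.6), lin-9 (59.0) and mes-2 (47.1). With a 1000 bp limit or with all protein-coding genes as background the list passed (adjusted p = 0.0303 and 0.0161 by Fisher's exact test). It did not pass in the other settings: 3 of 19 genes (15.8%) in replicate 3 alone (adjusted p = 0.329), 5 of 20 in replicate 1 alone (0.0592), 3 of 20 with the nearest gene alone (0.466), a 250 bp limit (0.266), the 428 strongest regions (0.0568) and genes with a 3- or 4-letter symbol (0.149), all by Fisher's exact test. LIN-54, LIN-9 and LIN-53 are subunits of the DREAM complex, which contains LIN-35. Since lin-35 is mutated in this strain, these regions do not show where HPL-2 lies in animals with wild-type lin-35. The region at lin-54 also lies at the 5′ end of rpl-12, and that at lin-53 is nearest to the 5′ end of nra-2.

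Tissue lists gave few regions. None of the 22 intestine genes with a candidate region had a reproducible one, which allows a share of up to 13.6% (adjusted p = 0.454 by Fisher's exact test). Muscle had 0 of 7 (up to 42.9%) and hypodermis 0 of 8 (up to 37.5%). Germline genes had 1 of 18, mes-2, and neuron genes 1 of 12, snb-1 (signal 50.6), with an adjusted p of 1 by Fisher's exact test for these 4 lists. In the single libraries the intestine share was above that of other genes instead, without passing the test, with 3 of 17 genes (17.6%) in the top regions of replicate 3 and 2 of 23 (8.70%) in those of replicate 1. Genes of starvation, insulin signalling and autophagy had 3 of 22 (13.6%, adjusted p = 0.696 by Fisher's exact test): atg-18 (signal 57.2), lgg-2 (46.8) and hlh-30 (39.5). The gene hlh-30 had no top-857 region of either library at its 5′ end, and atg-18 had such a region in replicate 1 alone.

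The other families did not pass the test either. F-box and MATH-BTB genes had 4 of 121 (3.31%, adjusted p = 0.117 by Fisher's exact test), namely fbxb-85 (signal 68.2), fbxb-72 (66.4), fbxc-19 (49.6) and fbxa-108 (43.5). They were called under-represented with all protein-coding genes as background (adjusted p = 0.0165) and among genes with a 3- or 4-letter symbol (0.0224), both by Fisher's exact test. Nuclear hormone receptors had 5 of 109 (4.59%, adjusted p = 0.339 by Fisher's exact test), with nhr-47 (signal 55.3), nhr-68 (50.2), nhr-105 (42.0), nhr-66 (41.0) and nhr-256 (38.6). Cuticle collagens had 2 of 36, col-38 (signal 49.1) and col-85 (38.9). The region at col-38 also lies at the 5′ end of rpl-5, and that at col-85 lies beside a tRNA gene. Histones had 1 of 14, his-37 (signal 156), and homeobox factors 1 of 20, ceh-38 (59.9). Neuropeptides had 0 of 29, which allows up to 10.3%, and they were called under-represented with all protein-coding genes as background (adjusted p = 0.0356 by Fisher's exact test).

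**Figure D4:**
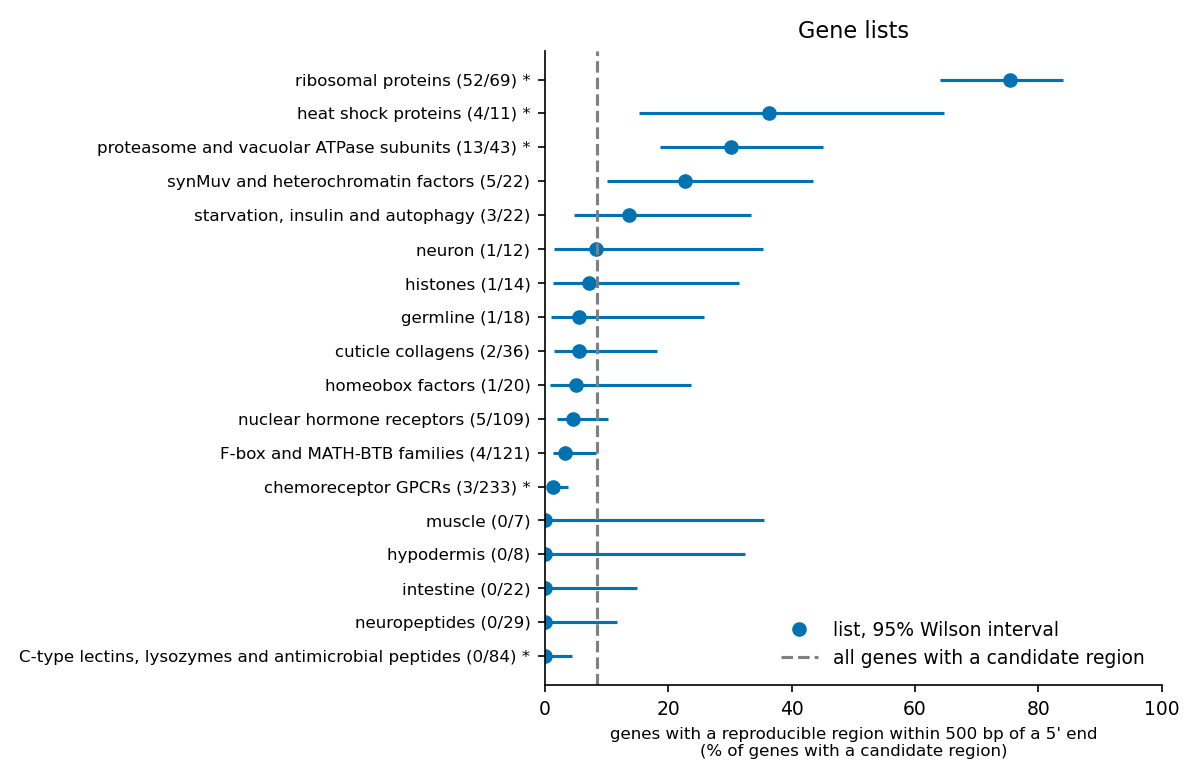
For each gene list, the point gives the percentage of its genes with a candidate region that have a reproducible region within 500 bp of a 5′ end, the line the 95% Wilson interval, and the label the counts. The dashed line is the 8.42% of all genes with a candidate region, asterisks mark adjusted p below 0.05, and ribosomal protein genes lie highest at 75.4%.

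The loci carried by the strain were inspected in every list. The genes that supply the array were without a candidate region in the pooled list and in both libraries: ges-1 (WBGene00001578, V 1427653 to 1432137), hpl-2 (WBGene00001996, III 10752195 to 10755530) and unc-119 (WBGene00006843, III 10902641 to 10908935). The gene lin-35 (WBGene00003020, I 5807709 to 5815637), mutated in this strain, had a reproducible region at its 5′ end with a signal of 60.6. It was among the top 857 regions of replicate 1 and not of replicate 3.

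On ce10, the thresholded set was smaller, with 766 regions, of which 139 were on III, 114 on V and 142 on X. Its weakest region had a signal of 39.9, and 766 of the ce11 regions had at least that signal. The 91 further regions in ce11 thus came from the lower cutoff of 37.9. At the same rank, the signals of the pooled lists on both builds differed by at most 0.566% within the top 766.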

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

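The setting that counts each gene only at its nearest region, the overlap null drawn from replicate 3 candidates and the motif background matched on GC were chosen after seeing the data. All other settings were fixed before the data were examined. Of 344 recomputed values, 289 kept their direction and their side of the threshold, or stayed within 1.5 times for counts. The 289 include items that passed the threshold in neither setting. They also include rRNA genes, which were at 0 in every setting and could not change, so the total is not a rate of robust calls. Among the 289 are replicate overlap (38.9% to 47.2%), and the promoter, distal, GC and masked-repeat differences in every setting run. With nothing but the top regions of 1 library, the promoter difference was 23.6 to 27.6 percentage points. The number of regions was 857, 766 on ce10, 843 after merging overlaps, and 600 of the 857 overlapping the top 1714 of both libraries. With 2 libraries, leaving out either leaves the other's own ranking, and depth is unknown, so no weaker binding can be excluded.

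The X share, which differed from background by −0.422 percentage points in the reproducible set, reversed to 2.99 among the 428 strongest regions and 0.275 on ce10, and ranged from −0.766 to 0.676 over the single libraries. The log2 signal difference of promoter regions reversed to −0.0224 at 250 bp, −0.0238 with replicate 1 signals and −0.108 with replicate 3 signals. None of these passed the threshold, before or after. Counts of called items moved as follows. Under-represented noncoding classes went from 2 to 1 among the 428 strongest regions. Under-represented motifs ranged from 3 to 5 over the single libraries, against 5. With the background matched on GC they were 0, and over-represented motifs 3, against 4. Over the single libraries, over-represented gene lists ranged from 1 to 3, against 3, and under-represented lists from 1 to 2, against 2. Over-represented lists were 4 at 1000 bp and with all protein-coding genes as background, and 2 among the 428 strongest regions, at 250 bp, among genes with a 3- or 4-letter symbol and with the nearest gene alone. Under-represented lists were 1 among the 428 strongest regions, 1 at 250 bp, 3 among genes with a 3- or 4-letter symbol and 4 with all protein-coding genes as background.

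Differences of single items also reversed, none past the threshold after the change, in percentage points. Among the 428 strongest regions these were AP-1 (0.0714), histones (2.70) and homeobox factors (0.554). With the background matched on GC they were extended GATA (0.993), CHR (2.39) and the T tract (0.117). Over the single libraries, the ranges were −4.20 to 2.62 for extended GATA, −0.230 to 1.01 for AP-1, 0.534 to 10.2 for intestine, −7.46 to 0.929 for neuron, −0.759 to 3.08 for starvation genes and −0.472 to 2.55 for histones. At 250 bp they were germline (1.34), starvation genes (−2.21) and histones (2.25), and at 1000 bp germline (1.06). Neuron genes reversed to 0.109 with all genes as background and 1.45 with the nearest gene alone, where histones gave 3.11. The gene list reversals rest on 0 to 3 genes per list.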

Other observations

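Tests chosen only after the result was seen are the comparison with small RNA genes, the comparison of whole candidate lists and the count of intestine genes, as are the values of the next paragraph. The core motif tests and the GC tests were written down before their results were seen, for patterns noticed in the data.

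The snRNA genes beside reproducible regions included spliced leader genes of the sls-2 family, 7 of the 13. Those with the strongest regions were sls-2.1 (II 5844865 to 5844974, signal 182), sls-2.2 (II 5543598 to 5543707, 181), sls-2.4 (I 4172206 to 4172315, 145) and sls-2.8 (III 12250465 to 12250575, 106). The fifth was sup-6, with a signal of 99.1. The 6 regions near miRNA genes lay at 5 genes, and the strongest of these was cel-mir-5549 (III 6971976 to 6972085, signal 92.1), followed by cel-mir-80 (signal 47.1). Among tRNA genes with a candidate region, 23 of 166 on X (13.9%) and 18 of 187 on autosomes (9.63%) had a reproducible one (Fisher's exact p = 0.246). The ges-1, hpl-2 and unc-119 loci lay in candidate-free stretches of 38167, 22392 and 32127 bp in the pooled list. A stretch at least as long surrounds 2.11%, 8.17% and 3.23% of protein-coding genes. Array and native copies share these sequences, so the lists cannot tell them apart. The control file was not analysed, so its part in these stretches is unknown.

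Some of the strong regions on X outside promoters may be recruitment elements of the dosage compensation complex, which binds X in hermaphrodites at sites that share a short core sequence. The core GCGCAGGG was within 100 bp of the summit in 15 of 153 reproducible regions on X (9.80%) and 3 of 704 on autosomes (0.426%), a difference of 9.38 percentage points (Fisher's exact p = 1.64e-09), and 8 of the 12 X regions among the 20 strongest held it, among them those nearest to W02H3.3, ins-39, xol-1 and mom-1. X candidates matched on GC content carried it in 0.634% of cases, below the interval of the reproducible X regions (6.03 to 15.5%), which argues against GC-rich sequence as the cause. The difference was present in the top regions of each library, the smaller being 8.19 points, which argues against a property of 1 library. Whether HPL-2 itself is at these sites, or whether they appear in any ChIP of this kind, stays open, since no library of another factor or of tag alone was analysed here.

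The regions at ribosomal protein genes may reflect HPL-2 at active promoters, or open and heavily transcribed chromatin that is recovered whatever protein is tagged. GC content does not account for them: over deciles of GC, the Mantel-Haenszel odds ratio was 37.8 (18.5 to 77.4), against 36.0 without strata. Open chromatin remains possible, since neither openness nor transcription was measured here. Genes for tRNAs, snRNAs and snoRNAs, which are also heavily transcribed, were over-represented too, the smallest odds ratio being 3.39. Those values were known when the comparison was chosen, and they were not matched on GC. Regions can also be shared, as between rps-26 and the snoRNA gene F39B2.14, so the comparison cannot decide. A library of tag alone or of another factor would separate these readings, and none was analysed here.

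Replicate 3 had more extended GATA sites than replicate 1 among top regions not shared by the other library. The shares were 139 of 459 (30.3%) against 87 of 455 (19.1%), adjusted p = 0.000918 by Fisher's exact test over 10 motifs. T tracts were also more frequent (18.3% against 11.2%, adjusted p = 0.014 by Fisher's exact test). The scrambled control was not called different (6.10% against 4.62%, adjusted p = 0.421 by Fisher's exact test). Plain GATA was more frequent too (45.8% against 36.7%, adjusted p = 0.0196 by Fisher's exact test), but its pattern includes every extended site. These other motifs were not compared at matched GC content, so whether the excess is particular to GATA sites was not tested. Stratifying by GC content, which was lower in the replicate 3 regions, did not remove the difference for extended GATA. Over deciles of GC, the Mantel-Haenszel odds ratio fell from 1.84 to 1.44 and its interval (1.03 to 1.99) stayed just above 1. That interval was not adjusted for the choice of this motif among 10, and GC can differ within a decile. Lower GC content as the whole cause is therefore not excluded. A difference across the whole candidate list was not seen, with −0.0549 percentage points between the libraries outside the top regions. Sites of intestinal GATA factors remain an open source, since the top regions of replicate 3 alone were at 3 intestine genes (act-5, cpr-1, ifb-2) and those of replicate 1 alone at 2 (cpr-6, fat-6), too few to decide (Fisher's exact p = 0.659). Differences in staging, antibody lot or depth between the replicates were not tested.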
